A study of Homo sapiens with 12 samples.

How the data were processed

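RNA sequencing counts of 12 OE33 libraries were used, 3 for each of 4 groups: Parental, rABS, rABS_shCtrl (shCtrl) and rABS_shAPE1 (shAPE1). The study text describes 3 independent biological replicates per group, 15 days with a daily exposure of 20 minutes to bile salts (200 µM) acidified to pH 5.5, and later stable transduction of the survivors. RNA was selected for polyadenylation. The deposited values are raw counts per Ensembl gene, unnormalized whole numbers. Per the labels, the authors trimmed reads with Trimmomatic 0.36, aligned them to GRCh38 with STAR 2.5.2b and counted them with featureCounts of Subread 1.5.2. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here, so levels of near-identical paralogs may share reads. Of 57500 genes listed, 35464 had a count in some library, and 56898 were placed with GENCODE 29 positions.

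Library totals ran from 15736087 to 23010377. At this depth the APEX1 level in shAPE1, near 5 CPM, rested on 80 to 94 counts per library, and simulated 2-fold changes were recovered at the rate given with the simulations.

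Genes were kept with filterByExpr of edgeR over the 4 groups (minimum count 10, minimum total count 15), which left 15805. Libraries were scaled with TMM, and a quasi-likelihood model with robust dispersion and a term per group was fitted to all 12 libraries (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values use the scaled library sizes, except the sums and means of cell type markers, which use unscaled totals. For log2 CPM a prior count of 2 was used. The comparisons were rABS against Parental, shAPE1 against shCtrl, and shCtrl against rABS. APEX1 was also tested by exact permutation.

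The groups, tests, comparisons, 42 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 measured members, 39 of them, were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Adjustment was over the lists of a comparison. Named genes were APEX1, the 8 largest rises and falls among called genes at 5 CPM or more in a group with no overlap between the groups, up to 4 members per described list by adjusted p, and 5 genes per opposite direction. Genes withheld for evaluation are left out of the text. KRT6A had 3 counts in Parental, so its level is given as counts there.

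3' untranslated regions were taken from GENCODE 29 (longest per gene, at least 50 bases), and each 7-mer with at least 100 carriers was scored by the shift of its carriers after adjustment for length, GC content and expression. Shifts were compared with those of 7-mers of the same base composition, with 5 standard deviations as the bound. Neighbouring genes were examined in windows of 25 against 100 permuted gene orders. These searches were designed after the gene calls were seen.

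The procedure was tested on simulated data. Of genes changed 1.5-, 2- and 4-fold, edgeR recovered 74%, 91% and 100%, with 12 of 190 calls false. The simulation changed 50, 100 and 50 genes at these folds, all at a mean of at least 1 CPM, with 15428 tested. That is a far smaller share than was called in the data, so these rates need not hold for the comparisons here.

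Alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma-voom, other filters, a fit of the 6 libraries alone, rABS without a vector as the control of shAPE1, a replicate block, leaving out each library, a fold threshold, and other list tests. A covariate for small non-coding RNA share, a wider set of 7-mers and the restriction to genes without a seed match were added after the data were seen. For lists, that restriction limited the comparison genes as well as the members, and the libraries were rescaled on the remaining genes. Protein levels, APE1 activity and the hairpin sequence were not used here.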

Results

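The series asked what APE1, the base excision repair endonuclease and redox factor encoded by APEX1, contributes to the transcriptional state of esophageal adenocarcinoma cells after repeated reflux-like exposure. OE33 cells were compared in 4 groups of 3 libraries: untreated (Parental), survivors of 15 days of daily acidified bile salts (rABS), and rABS cells carrying a non-targeting (shCtrl) or an APE1-directed (shAPE1) short hairpin RNA. Library totals ran from 15736087 to 23010377 counts, and 15805 genes had enough counts to be tested. The first principal component of log2 CPM, counts scaled by library size, held 43.3% of the variance and the second 21.5%. Replicates of a group correlated at 0.987 or higher.

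APEX1 (chromosome 14, 20455191 to 20457772, plus strand, GRCh38) was measured in every library. Its level was 52.9, 54.3 and 56.9 CPM in Parental, 81.8, 84.5 and 79.9 in rABS, 62.0, 56.5 and 60.9 in shCtrl, and 4.42, 4.50 and 5.88 in shAPE1. Between rABS and Parental it rose 1.5-fold (log2 0.58 ± 0.08, standard error, n = 3 per group, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.23e-07). Between shAPE1 and shCtrl it fell 12.2-fold, to 8.2% of the shCtrl level (adjusted p = 3.75e-22). Between shCtrl and rABS it fell to 72.8% (adjusted p = 3.75e-05). The exact permutation test gave p = 0.1 in each comparison, the smallest value that 20 arrangements of 3 against 3 libraries can give.

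**Figure D1:**
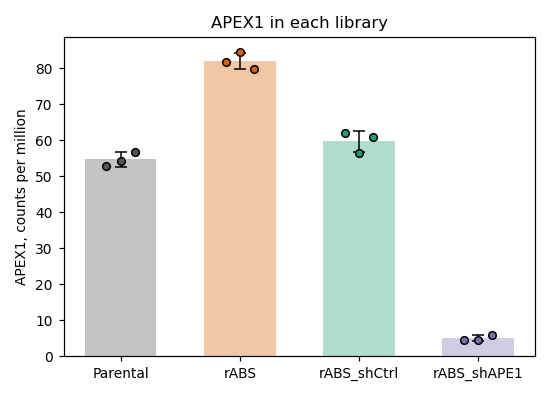
APEX1 in each of the 12 libraries, in CPM. Bars are group means, whiskers are standard deviations (n = 3), and points are libraries.

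The comparison of rABS with Parental addressed what differed after the 15 days of exposure and survival. None of the 4 groups was mock-treated, so effects of culture and passage over those days cannot be told apart from exposure here. Genes of the integrated stress response were far lower in the exposed survivors: ASNS, asparagine synthetase, fell 30.3-fold, from 659.9 ± 29.9 to 21.8 ± 1.12 CPM (mean and standard deviation, n = 3). DNA replication genes were higher, with the sliding clamp gene PCNA rising 5.63-fold, from 80.6 ± 1.68 to 454 ± 6.08 CPM. The extracellular matrix proteoglycan gene VCAN rose 26.2-fold, and THBD, which encodes the anticoagulant receptor thrombomodulin, fell 26.5-fold. In all, 4729 genes rose and 4725 fell, 59.8% of those tested, and 1602 and 1472 of them changed at least 2-fold.

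Among the largest rises, LINC02474, a long non-coding RNA gene on chromosome 1 (221966341 to 221984964), had no count in Parental and 7.28 ± 0.924 CPM in rABS, at least 128-fold higher against a floor of 3 counts per group. The stress keratin gene KRT6A had 461 counts in rABS and 3 in Parental. SERPINB2, a plasminogen activator inhibitor gene, rose 61.4-fold, SLC43A3, a purine nucleobase transporter gene, 58.1-fold, and EDAR, the ectodysplasin receptor gene, 45.4-fold. UGT2B7, which encodes a glucuronosyltransferase that acts on bile acids among other substrates, rose 28-fold. GAS6, which encodes the ligand of the receptor AXL, rose 26-fold. Among the largest falls were ULBP1, a ligand gene of the natural killer receptor NKG2D (56-fold), and ADM2, an adrenomedullin-family peptide gene (37.3-fold). UGT1A10 fell 27.5-fold, INHBE, an activin subunit gene, 26.5-fold, TIAM1, a RAC1 exchange factor gene, 25.4-fold, and SYNE3, a nuclear envelope protein gene, 24.4-fold. UGT1A10 shares its last exons with the other UGT1A genes. Several of these folds rest on low levels in 1 group and are imprecise, among them SLC43A3 (0.133 CPM in Parental), ULBP1 (0.091 in rABS) and INHBE (0.18 in rABS).

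Gene lists chosen before the data were examined were then tested (camera, preset correlation 0.01), and 21 of 39 changed, 12 up and 9 down. Of these, 8 held with an estimated correlation. The same test called at most 17 lists in other splits of the 6 libraries, which mix both groups and so give no null rate. All 31 DNA replication genes rose (median log2 1.74, adjusted p = 4.12e-17, 0.0116 with an estimated correlation). MCM2, MCM3 and MCM4, helicase subunits, rose 7.97-, 5.69- and 5.1-fold. Homologous recombination and Fanconi genes rose in 22 of 24 cases, with 2 not called (median 1.06, adjusted p = 1.26e-08, 0.0317 with an estimated correlation). XRCC2 rose 5.04-fold, FANCA 3.71-fold, the exonuclease gene EXO1 3.59-fold and the helicase gene BRIP1 3.1-fold. In base excision repair 14 of 21 genes rose, 2 fell and 5 were not called (median 0.61, adjusted p = 0.000336, 0.0211 with an estimated correlation). FEN1, the flap endonuclease, rose 9.33-fold, the uracil glycosylase gene UNG 4.75-fold, PARP1 2.64-fold and APEX2, the paralog of APEX1, 1.82-fold. Replication-dependent histone mRNAs mostly lack poly(A) tails, so in these poly(A)-selected libraries their counts also depend on carry-over of other RNA. Replication-dependent histone genes rose in 24 of 26 cases (median 1.02, adjusted p = 1.02e-07), among them H1-1 4.66-fold and H1-5 3.31-fold, adjusted p = 0.365 with an estimated correlation. Mitosis genes rose in 19 of 30 cases and fell in 4 (median 0.38, adjusted p = 0.00673, adjusted p = 0.412 with an estimated correlation). ANLN rose 2-fold, FOXM1 1.96-fold and the proliferation marker gene MKI67 1.61-fold.

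Of 23 genes of ATF4 and the integrated stress response, 22 fell and 1 was not called (median -2.10, adjusted p = 4.06e-14, 0.00313 with an estimated correlation). ATF4 itself fell 5.89-fold, from 729 ± 30.1 to 124 ± 4.23 CPM. TRIB3, a pseudokinase gene that ATF4 induces, fell 11.8-fold, and DDIT4, an inhibitor gene of the kinase complex mTORC1, 12.1-fold. NRF2 and antioxidant genes fell in 22 of 29 cases and rose in 4 (24 and 4 when adjusted over the list alone; median -0.89, adjusted p = 1.85e-05, 0.0386 with an estimated correlation). The cystine transporter gene SLC7A11 fell 4.09-fold, the transporter gene ABCC3 2.51-fold, the transketolase gene TKT 2.27-fold and TXNRD1, thioredoxin reductase, 2.17-fold. Of 24 p53 targets, 14 fell and 4 rose (median -0.46, adjusted p = 0.0152, adjusted p = 0.0704 with an estimated correlation). GDF15, a stress-induced cytokine gene, fell 16.6-fold, from 2444 ± 233 to 147 ± 10.9 CPM, and SESN2 fell 9.21-fold. SESN2, and SLC7A11 among the NRF2 genes, are also members of the integrated stress response list, so these lists are not fully separate. Lysosome and autophagy genes fell in 15 of 27 cases and rose in 4 (median -0.25, adjusted p = 0.00566, adjusted p = 0.365 with an estimated correlation). ULK1, the kinase that starts autophagy, fell 5.48-fold, GABARAPL1 4.89-fold, MAP1LC3B 4.26-fold and the cholesterol exporter gene NPC1 3.65-fold.

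WNT target and intestinal stem cell genes rose in 15 of 17 cases and fell in none (median 1.15, adjusted p = 1.72e-05, 0.0171 with an estimated correlation). AXIN2 rose 12.9-fold, NKD1 5.95-fold and the ubiquitin ligase gene RNF43 3.09-fold, all feedback inhibitors of WNT signalling, and the cyclin gene CCND1 rose 2.4-fold. Of 25 MYC and ribosome biogenesis genes, 24 rose (median 0.94, adjusted p = 4.65e-10, 0.0171 with an estimated correlation), among them the spermidine synthase gene SRM (4.25-fold) and the nucleolar protein gene NOP56 (3.7-fold). Squamous epithelium markers rose in 12 of 14 cases and fell in 1 (median 1.47, adjusted p = 0.00114, 0.0317 with an estimated correlation). The cornified envelope genes SPRR2A and SPRR3 rose 9.17- and 5.03-fold, from 0.416 and 2.08 CPM. KRT15, a basal keratin gene and the most abundant member, fell 3.83-fold. Heat shock genes rose in 13 of 18 cases and fell in 1 (median 0.79, adjusted p = 0.000285, adjusted p = 0.0728 with an estimated correlation). HSPA1A rose 6.99-fold, HSPA1B, its near-identical paralog, 4.74-fold, and HSPH1 4.13-fold. Proteasome genes rose in 21 of 29 cases (22 adjusted over the list alone; median 0.45, adjusted p = 6.75e-05, adjusted p = 0.272 with an estimated correlation), with PSMD2 up 2.4-fold.

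Cholesterol synthesis and uptake genes rose in 14 of 24 cases and fell in 4 (median 0.33, adjusted p = 0.0216, adjusted p = 0.219 with an estimated correlation). DHCR7, a late enzyme gene of the pathway, rose 2.41-fold, while the regulator gene SREBF2 fell 2.05-fold. Glycolysis genes rose in 10 of 19 cases and fell in 3 (median 0.25, adjusted p = 0.0236, adjusted p = 0.537 with an estimated correlation), with LDHA and PGAM1 both up 3.18-fold. Immediate early and AP-1 genes fell in 19 of 28 cases and rose in 2 (19 and 3 adjusted over the list alone; median -0.66, adjusted p = 1.85e-05, adjusted p = 0.139 with an estimated correlation). The phosphatase gene DUSP5 fell 8.06-fold, and AREG and EREG, ligand genes of the EGF receptor, fell 4.89- and 4.67-fold. STAT3 and IL6-family targets fell in 12 of 17 cases and rose in 2 (median -0.51, adjusted p = 0.00566, adjusted p = 0.219 with an estimated correlation), with the cytokine gene LIF down 4.06-fold. YAP targets fell in 8 of 15 cases and rose in 1 (median -0.32, adjusted p = 0.043, adjusted p = 0.197 with an estimated correlation), with DLC1 down 3.98-fold and the tissue factor gene F3 2.63-fold. Apoptosis regulators fell in 12 of 23 cases and rose in 3 (median -0.25, adjusted p = 0.048, adjusted p = 0.139 with an estimated correlation), including BCL2L2 (2.92-fold) and BBC3 (2.8-fold). Cytosolic ribosomal protein genes fell in 16 of 36 cases (15 adjusted over the list alone; median -0.17, adjusted p = 0.0159, adjusted p = 0.562 with an estimated correlation), with RPL3 down 1.71-fold.

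Inflammatory and lineage genes moved both ways. NF-kB and cytokine genes rose in 12 and fell in 7 of 21 cases without a call as a set (adjusted p = 0.245). The chemokine gene CXCL1 rose 7.42-fold and IL32 4.89-fold, and the interleukin genes IL1A and IL1B fell 13.6- and 6.79-fold. Bile acid receptor and transport genes fell in 7 and rose in 3 of 16 cases (median -0.67, adjusted p = 0.148), with CYP24A1 down 2.92-fold and the bile acid and nucleotide exporter gene ABCC4 up 2.23-fold. Unfolded protein response genes rose in 11 and fell in 8 of 20 cases (median 0.20, adjusted p = 0.78), with the chaperone gene CALR up 2.65-fold and the sensor gene ERN1 down 6.2-fold. Type I interferon genes rose in 12 and fell in 6 of 28 cases (adjusted p = 0.284), and hypoxia genes rose in 9 and fell in 10 of 25 (adjusted p = 0.796), with VEGFA down 4.85-fold. Antigen presentation genes rose in 10 and fell in 5 of 21 cases (adjusted p = 0.179), with CD74, the invariant chain, up 9.05-fold. Epithelial adhesion genes fell in 11 and rose in 4 of 20 cases (adjusted p = 0.0861), among them the splicing regulator gene ESRP1 (2.78-fold). Gastric and intestinal markers were not called as sets (adjusted p = 0.78 and 0.705), and the gastric mucin gene MUC5AC fell 3.86-fold. Median and mean differed in sign for intestinal markers (0.01 and -0.44), gastric markers (-0.22 and 0.21) and growth factor receptors (-0.21 and 0.10).

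**Figure D2:**
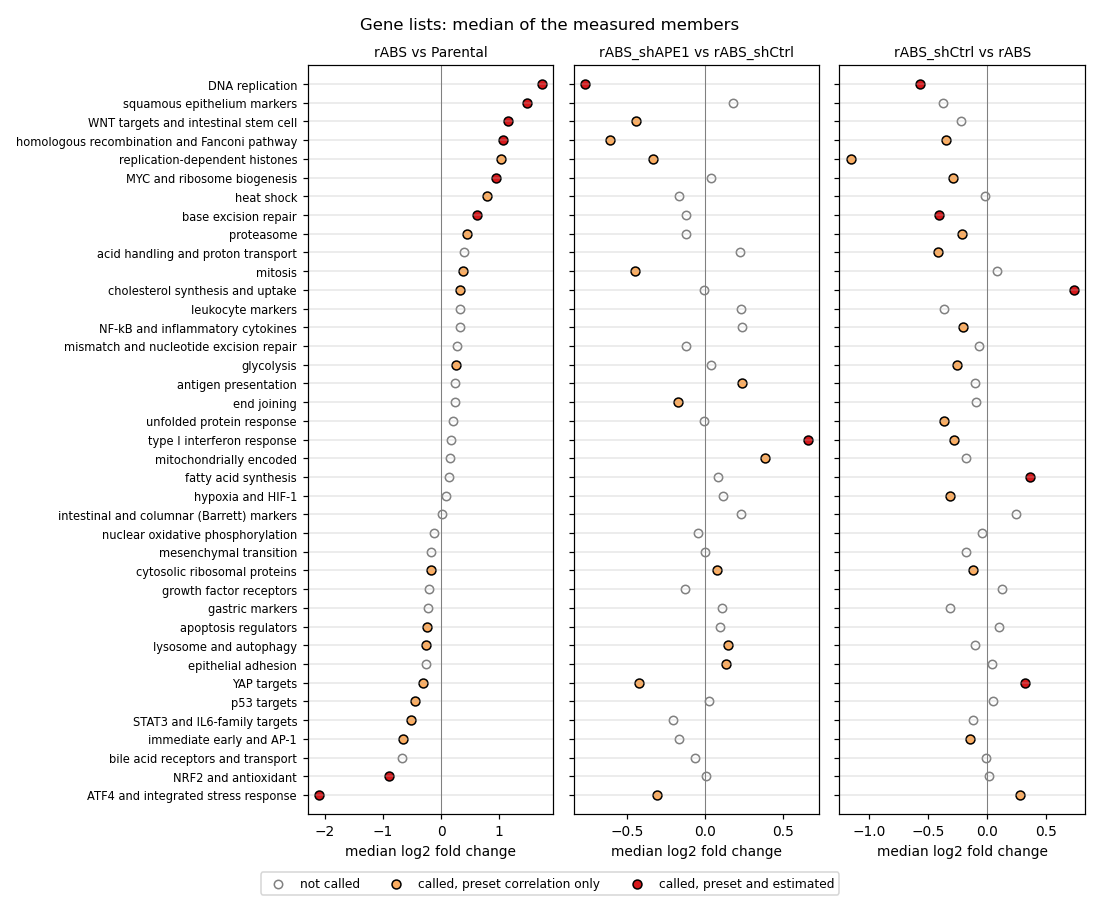
Median log2 fold change of each tested gene list in the 3 comparisons. White, not called; orange, called with the preset correlation alone; red, called with the preset and the estimated correlation (camera, adjusted p under 0.05).

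The comparison of shAPE1 with shCtrl addressed what the APE1 hairpin changed in exposed cells that carried a vector in both arms. DNA replication genes were lower with the APE1 hairpin: PCNA fell 2.21-fold, from 287 ± 4.20 to 130 ± 8.76 CPM (n = 3), and MCM2 also fell 2.21-fold. Interferon-response genes were higher, with OAS2, an antiviral synthetase gene, up 3.85-fold. CCL5, a T cell attracting chemokine gene, rose 7.55-fold, from a low level of 0.949 CPM to 7.18 CPM. PRKDC, which encodes the catalytic subunit of DNA-dependent protein kinase, fell 3.21-fold, from 676 ± 43.0 to 210.4 ± 8.89 CPM. In all, 2808 genes rose and 2976 fell, 36.6% of those tested, and 223 and 476 changed at least 2-fold. Which direction held more genes depended on the scaling, with 2990 rising and 2781 falling under RLE factors and 3215 and 2634 under upper-quartile factors. The labels describe a single APE1 hairpin, so changes from loss of APE1 and changes from other targets of that hairpin were not separated by the design. Neither were differences that arose between the transduced cell populations during transduction, selection and culture.

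After APEX1, the largest falls were EIF5A2, a translation factor gene (5.93-fold), EPHB6, a kinase-inactive ephrin receptor gene (5.44-fold), LZTFL1, a regulator of ciliary trafficking (5.32-fold), and SERTAD4 (4.72-fold). AXL, a receptor tyrosine kinase gene, fell 4.7-fold, from 103 ± 4.53 to 21.9 ± 0.351 CPM, MORF4L2, a chromatin factor gene, 4.62-fold, and EPB41L4B 4.56-fold. The largest rises after CCL5 were the ubiquitin ligase gene NEURL3 (6.11-fold), the prostatic acid phosphatase gene ACP3 (5.52-fold), BNIP5 (5.43-fold) and LGALS9, galectin-9 (4.52-fold, 17.9 ± 2.48 to 80.9 ± 9.32 CPM). SPRR2A rose 4.16-fold and the neutrophil chemokine gene CXCL6 3.95-fold.

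Many of the falling genes shared short sequences in their 3' untranslated regions. Among 15855 7-mers searched in 12448 genes, carriers of TGCATTC were lowest, at -16.85 standard deviations from 7-mers of the same base composition. TGCATTC occurs once in the APEX1 3' untranslated region (chromosome 14, 20457590 to 20457596), and 11% of all 7-mers occur in APEX1 transcripts. Together with the next 7-mers, GCATTCT and CTGCATT, which overlap it, it is called a seed match here; this set of 3 was chosen after the search was seen. In all 15 7-mers passed the bound of 5 standard deviations, among them GCATTCA (-12.13) and TGCATTA (-10.11), so genes without a match can still carry another of these. A seed match was present in 28.9% of searched genes, in 66.8% of those that fell at least 2-fold (256 of 383) and in 15.7% of those that rose at least 2-fold. These shares are not adjusted for length, GC content or expression, and the 7-mers were picked from these same fold changes. Unadjusted shares can differ widely: between shCtrl and rABS, AAAAATT was in 47.21% of called rises and 28.08% of called falls. Its adjusted mean log2 shift was -0.01, where that of TGCATTC here was -0.208. EIF5A2, EPHB6, LZTFL1, SERTAD4, AXL and MORF4L2 carried a match and EPB41L4B did not; of the 8 largest rises only BNIP5 carried one. Of 3594 genes with a match, 1325 fell and 526 rose (median log2 -0.16). Of 8854 without, 1405 fell and 2138 rose (median 0.04).

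Of the 39 lists tested, 14 changed, 6 up and 8 down, and 2 held with an estimated correlation, DNA replication and the type I interferon response. The same test called at most 8 lists in other splits of the 6 libraries, which again mix both groups and give no null rate. DNA replication genes fell in 30 of 31 cases (median -0.77, adjusted p = 1.81e-16, 0.0131 with an estimated correlation). Of the 22 members without a seed match, 21 fell (median -0.67, 95% interval -0.80 to -0.53), and all 9 with a match fell (median -1.01). The 16 members with none of the 15 7-mers all fell (median -0.57, 95% interval -0.82 to -0.50). MCM2, PCNA and the licensing factor gene CDC6 (2.16-fold) carried a match, and MCM7 (1.81-fold) did not. Homologous recombination and Fanconi genes fell in 21 of 24 cases (22 adjusted over the list alone; median -0.61, adjusted p = 3.91e-09, adjusted p = 0.0573 with an estimated correlation). The helicase gene BLM fell 2.23-fold, BRCA1 1.82-fold, EXO1 1.79-fold and FANCI 1.73-fold, and none of these 4 carried a match. Mitosis genes fell in 26 of 30 cases and rose in 1 (27 and 1 adjusted over the list alone; median -0.45, adjusted p = 1.24e-08, adjusted p = 0.206 with an estimated correlation). PTTG1, securin, fell 2.61-fold and carried a match, and TOP2A, topoisomerase II alpha, fell 1.57-fold without a match. Replication-dependent histone genes fell in 18 of 26 cases (20 adjusted over the list alone; median -0.33, adjusted p = 0.00024, adjusted p = 0.617 with an estimated correlation), with H1-5 down 1.49-fold.

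Of the 21 base excision repair genes 7 fell, APEX1 among them, 1 rose and 13 were not called, without a call as a set (median -0.12, adjusted p = 0.0744). The 18 searched members without a seed match were called lower (6 fell and 0 rose, median -0.14, adjusted p = 0.0185) at the preset correlation alone. The whole list had adjusted p = 0.21 with an estimated correlation, and the subset was not tested that way. Here and below, tests of members without a match compared them with other searched genes without a match, not with all genes. In the main fit those genes had a median of 0.036, and all tested genes -0.02. A call gained or lost in such a subset therefore need not come from matches in the members. FEN1 fell 1.64-fold and UNG 1.42-fold, neither with a match, and the ligase gene LIG3 rose 1.23-fold with a match. End joining genes fell in 6 of 13 cases and rose in 1 (7 and 1 adjusted over the list alone; median -0.18, adjusted p = 0.0484, adjusted p = 0.21 with an estimated correlation). PRKDC, the ligase gene LIG4 (2.36-fold) and RIF1 (1.53-fold) carried a match, POLQ (1.38-fold) did not, and the 7 list members without a match gave no call as a set (adjusted p = 0.314).

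Type I interferon genes rose in 17 of 28 cases and fell in 2 (18 and 2 adjusted over the list alone; median 0.66, adjusted p = 1.36e-06, 0.0131 with an estimated correlation). The antiviral genes IFIT3, IFIT2 and OAS1 rose 2.18-, 2.12- and 1.7-fold, and none carried a match. Antigen presentation genes rose in 12 of 21 cases and fell in none (median 0.24, adjusted p = 0.000656, adjusted p = 0.25 with an estimated correlation). CD74 rose 1.81-fold, the transcription factor gene IRF1 1.57-fold, the immunoproteasome gene PSMB10 1.43-fold and HLA-E 1.29-fold, all without a match. NF-kB and cytokine genes rose in 11 and fell in 6 of 21 cases without a call as a set (adjusted p = 0.154). CXCL3 rose 2.97-fold, and IL1B fell 3.48-fold, both without a match; IL1A (3.38-fold) and NFKB1 (1.83-fold) fell and carried a match, as did STAT3 (2-fold).

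Integrated stress response genes fell in 13 of 23 cases and rose in 3 (13 and 4 adjusted over the list alone; median -0.31, adjusted p = 0.00856, adjusted p = 0.157 with an estimated correlation). The serine synthesis genes PHGDH and PSAT1 fell 3.61- and 2.19-fold and ASNS 2.23-fold, none with a match, and MTHFD2, a mitochondrial folate enzyme gene, fell 1.99-fold with a match. YAP targets fell in 10 of 15 cases and rose in 2 (median -0.42, adjusted p = 0.00052, adjusted p = 0.0612 with an estimated correlation). NT5E, the surface nucleotidase CD73, fell 3.95-fold and F3 2.15-fold, both with a match, and DLC1 fell 1.9-fold without. The 8 YAP targets with a match had a median of -0.91, and the 7 without -0.23 (95% interval -0.93 to 0.17, adjusted p = 0.0419 at the preset correlation). WNT target and stem cell genes fell in 10 of 17 cases and rose in 3 (11 and 3 adjusted over the list alone; median -0.44, adjusted p = 0.034, adjusted p = 0.206 with an estimated correlation). TCF7 fell 2.35-fold and BMI1 2.2-fold, both with a match, SOX9 fell 1.7-fold and MYC rose 1.57-fold, both without; the 10 members without a match gave no call as a set (adjusted p = 0.437).

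Epithelial adhesion genes rose in 9 of 20 cases and fell in 3 (median 0.13, adjusted p = 0.0113, adjusted p = 0.25 with an estimated correlation). The junction gene TJP3 rose 1.66-fold, RAB25 1.58-fold and CLDN4 1.4-fold; the 15 members without a match gave no call as a set (adjusted p = 0.0754). Lysosome and autophagy genes rose in 12 of 27 cases and fell in 3 (12 and 4 adjusted over the list alone; median 0.15, adjusted p = 0.0241, adjusted p = 0.538 with an estimated correlation), with ATG9A up 1.55-fold. Mitochondrially encoded genes rose in 3 of 13 cases (2 adjusted over the list alone; median 0.38, adjusted p = 0.00993, adjusted p = 0.617 with an estimated correlation), with MT-ND2 up 1.45-fold. Cytosolic ribosomal protein genes rose in 9 of 36 cases (median 0.08, adjusted p = 0.0484, adjusted p = 0.684 with an estimated correlation), with RPS2 up 1.29-fold; without matches the set was not called (adjusted p = 0.155). Proteasome genes fell in 11 of 29 cases and rose in 1 (12 and 2 adjusted over the list alone) without a call as a set (adjusted p = 0.0744), and the 23 members without a match were called lower at the preset correlation alone (median -0.12, adjusted p = 0.0175). The whole proteasome list had adjusted p = 0.617 with an estimated correlation, and the subset was not tested that way. The changed comparison genes matter for these calls. From the whole list to members without a match, the proteasome median went from -0.126 to -0.118. The ribosomal protein median went from 0.078 to 0.102 and the adhesion median from 0.132 to 0.141, although both lists lost their calls. NRF2 and antioxidant genes were not called as a set (adjusted p = 0.178), although FTH1, ferritin heavy chain, rose 2.28-fold. Median and mean, or mean and test, differed in sign for glycolysis (0.04 and -0.03), cholesterol genes (-0.01 and -0.02, tested up), bile acid genes (-0.06 and 0.18), mesenchymal genes (0.00 and -0.12) and apoptosis regulators (0.10 and -0.004).

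**Figure D3:**
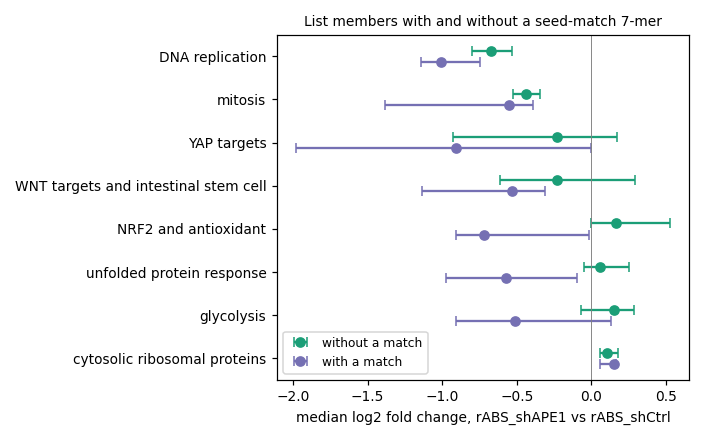
Median log2 fold change between shAPE1 and shCtrl of list members with and without a seed match in the 3' untranslated region, with 95% bootstrap intervals, for 8 lists.

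The comparison of shCtrl with rABS addressed what transduction, selection and added culture changed, the background of the APE1 comparison. Sterol and lipid synthesis genes were higher in shCtrl: INSIG1, a sterol-sensing regulator gene, rose 2.98-fold, from 19.9 ± 1.89 to 59.5 ± 3.28 CPM (n = 3), and SREBF2 rose 2.68-fold. The histone H4 genes H4C12 and H4C11 fell 6.86- and 6.49-fold. The immediate early genes FOSB and FOS fell 8.52- and 6.88-fold. In all, 2832 genes rose and 2935 fell, 36.5% of those tested (3005 and 2750 under upper-quartile factors), and 525 and 242 changed at least 2-fold.

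ANKRD1, a YAP target gene, rose 7-fold, and ACSM3, a medium-chain acyl-CoA ligase gene, 5.9-fold. MUC3A, a membrane mucin gene, rose 4.39-fold, PADI3 4.36-fold, ASNS 3.88-fold, ADIRF-AS1 3.62-fold and the glucose transporter gene SLC2A3 3.5-fold. KRT6A fell 18.6-fold, from 8.46 ± 0.307 to 0.448 ± 0.0914 CPM, the myosin light chain gene MYL9 4.66-fold, SNPH 4.64-fold and TCIM 3.92-fold.

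Of the 39 lists, 18 changed, 4 up and 14 down, and 5 held with an estimated correlation. Other splits of the 6 libraries, which mix both groups and give no null rate, gave at most 12. Cholesterol genes rose in 18 of 24 cases and fell in 1 (median 0.73, adjusted p = 2.14e-09, 0.0133 with an estimated correlation), with the enzyme genes MSMO1 and FDFT1 up 2.71- and 2.41-fold. Fatty acid synthesis genes rose in 12 of 13 cases (median 0.36, adjusted p = 4.01e-06, 0.0133 with an estimated correlation), with the desaturase gene SCD up 2.1-fold and ACSS2 1.83-fold. YAP targets rose in 11 of 15 cases and fell in 1 (median 0.32, adjusted p = 0.000129, 0.036 with an estimated correlation), with DLC1 up 2.29-fold, AXL 1.69-fold and TEAD1 1.63-fold. DNA replication genes fell in 28 of 31 cases (median -0.56, adjusted p = 1.32e-14, 0.0133 with an estimated correlation), with the ribonucleotide reductase gene RRM2 down 2.1-fold, CDC45 2-fold, MCM2 1.75-fold and PCNA 1.58-fold. Base excision repair genes fell in 12 of 21 cases (13 adjusted over the list alone; median -0.41, adjusted p = 6.77e-05, 0.0133 with an estimated correlation), with FEN1 and OGG1, the 8-oxoguanine glycosylase, both down 1.8-fold.

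All 26 histone genes fell (median -1.15, adjusted p = 1.77e-20, adjusted p = 0.105 with an estimated correlation), with H4C8 down 3.06-fold and H1-1 2.77-fold, under the same limit of poly(A) selection. Homologous recombination genes fell in 15 of 24 cases (17 adjusted over the list alone; median -0.35, adjusted p = 4.12e-05, adjusted p = 0.0723 with an estimated correlation). Unfolded protein response genes fell in 13 of 20 cases and rose in 3 (14 and 3 adjusted over the list alone; median -0.37, adjusted p = 0.000132, adjusted p = 0.0632 with an estimated correlation), with HSPA5, the endoplasmic reticulum chaperone BiP, down 2.2-fold. Integrated stress response genes rose in 12 of 23 cases and fell in 2 (median 0.28, adjusted p = 0.00304, adjusted p = 0.0632 with an estimated correlation). NF-kB and cytokine genes fell in 9 of 21 cases and rose in 4 (12 and 4 adjusted over the list alone; median -0.21, adjusted p = 0.00552, adjusted p = 0.0597 with an estimated correlation), with CXCL2 down 3.14-fold and CXCL1 2.22-fold. Immediate early genes fell in 12 of 28 cases and rose in 7 (median -0.14, adjusted p = 0.0468, adjusted p = 0.512 with an estimated correlation), with JUN down 3.86-fold and EGR1 2.81-fold. Glycolysis genes fell in 13 of 19 cases and rose in 2 (median -0.25, adjusted p = 0.000668, adjusted p = 0.498 with an estimated correlation), and hypoxia genes fell in 13 of 25 and rose in 6 (14 and 6 adjusted over the list alone; median -0.31, adjusted p = 0.0139, adjusted p = 0.0632 with an estimated correlation). PGAM1 fell 1.62-fold and the hydroxylase gene EGLN3 2.18-fold.

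MYC and ribosome biogenesis genes fell in 15 of 25 cases and rose in 1 (median -0.29, adjusted p = 6.78e-05, adjusted p = 0.0632 with an estimated correlation), with SRM down 1.63-fold. Proteasome genes fell in 17 of 29 cases (median -0.21, adjusted p = 4.01e-06, adjusted p = 0.184 with an estimated correlation), with PSMC4 down 1.57-fold. Type I interferon genes fell in 9 of 28 cases and rose in 1 (10 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.0329, adjusted p = 0.0723 with an estimated correlation), with IRF7 down 1.94-fold. Acid handling and proton transport genes fell in 7 of 13 cases and rose in 2 (median -0.41, adjusted p = 0.0203, adjusted p = 0.0723 with an estimated correlation), with the anion exchanger gene SLC4A2 down 1.98-fold. Cytosolic ribosomal protein genes fell in 6 of 36 cases (4 adjusted over the list alone; median -0.12, adjusted p = 0.0329, adjusted p = 0.716 with an estimated correlation). Median and mean, or mean and test, differed in sign for p53 targets (0.05 and -0.02), NRF2 genes (0.02 and -0.01), antigen presentation genes (-0.10 and 0.07) and bile acid genes (-0.005 and 0.14).

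**Figure D4:**
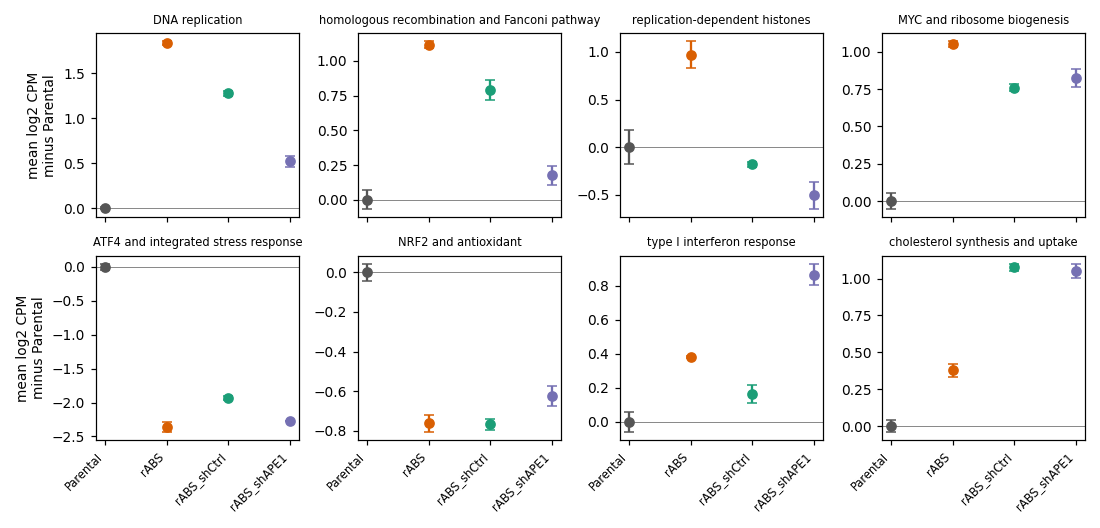
Mean log2 level of 8 gene lists in each group relative to Parental, with standard deviations over libraries (n = 3).

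Against Parental, DNA replication genes stood at a mean log2 of 1.84 ± 0.02 in rABS, 1.28 ± 0.03 in shCtrl and 0.52 ± 0.06 in shAPE1. Integrated stress response genes stayed low throughout, at -2.36, -1.93 and -2.27 in the same order. Interferon genes stood at 0.38, 0.17 and 0.86, and cholesterol genes at 0.38, 1.08 and 1.05.

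The change between Parental and rABS and that between shCtrl and shAPE1 were set against each other across genes, in comparisons that share no library. TXNIP, a thioredoxin inhibitor gene, fell 3.38-fold between Parental and rABS, from 656 ± 38.2 to 194 ± 8.33 CPM. It rose 3.03-fold between shCtrl and shAPE1, from 173 ± 6.86 to 524 ± 26.7 CPM. The guanylate-binding protein gene GBP2 fell 3.16-fold and then rose 2.9-fold, NEURL3 fell 4.15-fold and rose 6.11-fold, SDCBP2 fell 3.76-fold and rose 2.63-fold, and the autophagy gene ATG9B fell 5.58-fold and rose 2.51-fold. None of these 5 carried a seed match. EPHB6 rose 4.01-fold and fell 5.44-fold, TMEM158 rose 5.38-fold and fell 3.52-fold, and MT1E, a metallothionein gene, rose 4.86-fold and fell 3.28-fold. TNS4, a focal adhesion protein gene, rose 4.77-fold and fell 3.48-fold, and the microtubule-severing gene KATNAL1 rose 3.02-fold and fell 3.13-fold. EPHB6, MT1E and KATNAL1 carried a match, and TMEM158 and TNS4 did not.

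In all, 1336 genes rose between Parental and rABS and fell between shCtrl and shAPE1. From the counts of each, 890.4 were expected (odds ratio 2.27, 95% interval 2.08 to 2.46). A further 1251 fell and then rose, where 839.5 were expected (odds ratio 2.2, 2.02 to 2.4). Of the genes called in both comparisons, 2587 moved in opposite directions and 1658 in the same direction, 60.9% opposite. At a 2-fold change in both, 167 were opposite and 112 the same, and each pattern exceeded its expected count. Of the opposite genes 110 rose and then fell (48.3 expected, odds ratio 2.79, 2.22 to 3.48) and 57 fell and then rose (20.8 expected, odds ratio 3.44, 2.49 to 4.7). Of the others 46 rose in both (22.6 expected, odds ratio 2.34, 1.65 to 3.27) and 66 fell in both (44.3 expected, odds ratio 1.59, 1.2 to 2.08). Without the fold threshold 802 rose in both (840.2 expected) and 856 fell in both (889.7 expected). Across genes the log2 fold changes correlated at -0.106 (Pearson) and -0.131 (Spearman). Genes are not independent replicates. The odds ratio intervals above treat genes as independent, so those intervals do not measure the spread between libraries. Among the 8854 searched genes without a seed match, 1637 moved in opposite directions and 981 in the same direction. Some movement back toward Parental came without the APE1 hairpin. Between rABS and shCtrl, DNA replication genes also fell in 28 of 31 cases and rose in 0 (median -0.56). Mitosis genes fell in 5 of 30 cases there and rose in 10. How many of the opposite genes had already moved back in shCtrl was not counted.

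**Figure D5:**
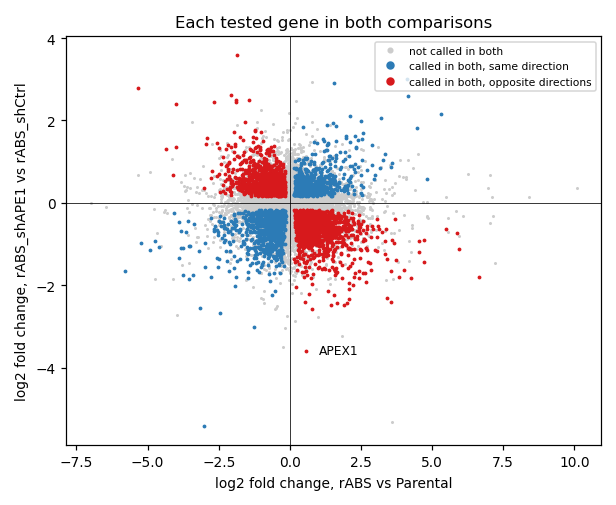
Log2 fold change between shAPE1 and shCtrl against that between rABS and Parental, each point a gene.

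Markers of cell types other than epithelium were summed in each group, in CPM of unscaled library totals, unlike the CPM values above. Summed fibroblast markers were 25.4 CPM in Parental, 4.21 in rABS, 10.9 in shCtrl and 8.79 in shAPE1, with 2 of 12 genes past the expression filter and COL1A1 the highest. Leukocyte markers summed to 11.5, 28.3, 16.1 and 19.4 CPM, with CD79A the highest. Endothelial markers summed to 62.3, 57.8, 58.8 and 54.9 CPM, with EGFL7 the highest (mean 40.8), and neural and kidney-derived markers to 46.4, 87.1, 81.6 and 76.9 CPM, with GATA2 the highest (mean 37).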

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

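The small non-coding RNA covariate and the restriction to genes without a seed match were chosen after the data were seen; the other alternatives were planned. No named gene or list result reversed under the alternatives run for it. Of 6500 checks on 500 named-gene results, 6456 kept direction and call and 44 kept direction without passing the threshold. The naming rule favoured the largest changes and smallest adjusted p in the main fit of these libraries, so high survival was built in. Among all called genes, leaving out 1 library kept as few as 8613 of 9454 for rABS vs Parental. The lowest were 4630 of 5784 for shAPE1 vs shCtrl and 4474 of 5767 for shCtrl vs rABS. Of 543 checks on 53 list results, 475 kept both and 68 lost the call, 38 of them with the estimated correlation.

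Requiring a 2-fold change lowered the counts by construction, to 3074 genes for rABS vs Parental, 699 for shAPE1 vs shCtrl, 767 for shCtrl vs rABS and 167 for opposite directions. Restricting the test to genes without a seed match tests fewer genes and gave 3596 changed between shAPE1 and shCtrl, 2162 higher and 1434 lower, where all genes gave 2808 higher and 2976 lower. The same restriction gave 1637 genes in opposite directions and 11 changed lists, these tested against genes without a match only. With an estimated correlation 8, 2 and 5 lists changed in the 3 comparisons, in place of 21, 14 and 18. Correlated members are not the whole cause. Between shAPE1 and shCtrl the interferon list had an estimated correlation of -0.0196, under the preset 0.01, yet its adjusted p went from 1.36e-06 to 0.0131. Between rABS and Parental, p53 targets (-0.0186) and apoptosis regulators (-0.0106) lost their calls. Other differences between the 2 settings were not tested. With fry, which does not compare a list with other genes, 35, 28 and 24 lists changed.

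With RLE factors 9440, 5771 and 5782 genes changed, with upper-quartile factors 9444, 5849 and 5755, with DESeq2 9335, 5699 and 5679 and with limma-voom 9404, 5779 and 5816. Without a low-count filter there were 9285, 5297 and 5346, and with the 6 libraries of each comparison alone 9190, 5811 and 6201. The small non-coding RNA covariate gave 9730, 6385 and 5396. Against rABS without a vector, shAPE1 changed 7896 genes, 3758 higher and 4138 lower, a comparison that also includes transduction and selection. DESeq2 kept 9312 of the 9454 genes called between rABS and Parental.

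The direction with more called genes turned in each comparison. Between shAPE1 and shCtrl more genes fell (2808 higher, 2976 lower), but more rose with RLE factors (2990 and 2781), upper-quartile factors (3215 and 2634), DESeq2 (2955 and 2744) and the 6 libraries alone (2991 and 2820). Between shCtrl and rABS (2832 and 2935) more rose with upper-quartile factors (3005 and 2750) and a filter at a mean of 1 CPM (2961 and 2697), as at a 2-fold change (525 and 242). Between rABS and Parental (4729 and 4725) more fell with that filter (4415 and 4487), limma-voom (4691 and 4713) and the replicate block (4624 and 4642).

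Leaving out 1 library at a time gave 8875 to 9108 genes for rABS vs Parental, 4779 to 5290 for shAPE1 vs shCtrl and 4650 to 5200 for shCtrl vs rABS. Opposite-direction genes ranged from 2160 to 2601, and lists from 18 to 21, 11 to 15 and 15 to 20. The log2 change of APEX1 ranged from 0.57 to 0.62, from -3.74 to -3.53 and from -0.49 to -0.42. Among the called lists, some leave-one-out fits lost YAP targets, glycolysis, apoptosis regulators and ribosomal proteins between rABS and Parental. End joining, ribosomal proteins and WNT targets were lost between shAPE1 and shCtrl, and ribosomal proteins, interferon and immediate early genes between shCtrl and rABS.

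A replicate block gave 9266, 5485 and 5457 genes, 21, 12 and 17 lists, 2428 opposite-direction genes, and APEX1 changes of 0.59, -3.61 and -0.46. The replicate numbers did not pair libraries: of 18 same-number pairs, 1 correlated above 0.1 (range -0.167 to 0.109). With 3 libraries per group at this depth, 74% of simulated 1.5-fold changes were recovered, in a simulation with a far smaller share of changed genes than was called here. Depth and replicate number were not varied.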

Other observations

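The tests of endoplasmic reticulum stress, library scaling and culture state were chosen after the result was seen, as were the set of 3 seed-match 7-mers and the wider set of 15; the other tests here were written before their results.

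Genes other than APEX1 that fell with the APE1 hairpin may include direct off-target genes, since carriers of TGCATTC lay at -16.85 standard deviations from 7-mers of the same composition, and that 7-mer occurs in the APEX1 3' untranslated region. The deviation of the same 7-mer was 0.53 and -0.49 in the other comparisons. The hairpin sequence was not used here, so the match to its guide was not tested. For DNA replication genes, matches in their own untranslated regions do not account for the fall: the 22 members without a match had a median of -0.671 (95% interval -0.802 to -0.53), and the 16 with none of the 15 7-mers beyond the bound had -0.575 (-0.822 to -0.5). An indirect effect, through an off-target gene upstream of them, stays open beside loss of APE1. A difference between the transduced and selected cell populations, apart from any hairpin target, stays open as well. Between shCtrl and rABS, without the APE1 hairpin, the same list fell in 28 of 31 cases (median -0.564).

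Gain or loss of chromosome segments could contribute to the changes between rABS and Parental, since 17 windows of 25 neighbouring genes lay beyond every permuted order. They form 2 segments, on chromosome 11 from 66.24 to 66.68 Mb (25 genes, extreme window median 0.96) and on chromosome 12 from 42.24 to 48.35 Mb (40 genes, -1.22). Against Parental the chromosome 11 genes had medians of 0.95 in rABS, 0.42 in shCtrl and 0.41 in shAPE1, and those on chromosome 12 -0.67, -0.37 and -0.54. The segments were chosen as extreme in rABS, and how much this choice inflates the rABS values was not tested. The smaller values in the other lines therefore do not decide for or against a copy change. The segments hold 48 of 9420 placed calls, 0.51%, so they cannot account for most of them. Regulation of neighbouring genes would give the same windows, and changes under a window median of 0.95 were not detectable.

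Between shCtrl and rABS 62 such windows form 1 segment on chromosome 6 from 24.4 to 28.4 Mb, which holds the histone gene cluster, and between shAPE1 and shCtrl there were 0.

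The fall of integrated stress response genes in rABS against Parental was weighed against 3 explanations. Library scaling does not account for it: a scaling factor shifts every gene of a library alike, and the median of the list lay at -2.092 from the median of all genes. Endoplasmic reticulum stress in the parental cells was not decided, since the unfolded protein response list had a median of 0.205 with an interval of -0.639 to 0.523. Culture state at harvest, such as density or nutrient supply, cannot be told apart from the exposure: each group comes from its own cultures, and the list also moved by 0.281 (interval 0.103 to 0.581) between shCtrl and rABS, which had the same exposure. The exposure itself stays among the open explanations.

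With 3 libraries against 3 there are 10 splits, so the share of splits with a result as large cannot fall under 0.05, and in each case only the real split, 1 of 10, gave as large a result. For genes the real values were 9454, 5784 and 5767, with 0 as the highest of the others. For lists they were 21, 14 and 18, with 17, 8 and 12 as the highest of the others. For genes in opposite directions the real value was 2587 and the highest other 0. Every other split put libraries of both groups on each side. Real differences between the groups then widen the spread within a side and also remain partly between the sides. The counts in other splits are therefore not a null rate, and no conclusion about chance is drawn from them.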
